A study of Mus musculus with 20 samples.

How the data were processed

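Skin of female mice was profiled on 20 two-colour oligonucleotide arrays, each set with the RNA of 1 pool in Cy3 and of another in Cy5. Per the labels, every pool held total RNA of 5 mice, and each pair of pools was hybridised on 2 arrays with the dyes exchanged. The arrays fall into 2 comparisons of 10, FVB/N abraded over FVB/N sham and Tg.AC abraded over FVB/N abraded, with 2 arrays on each of 5 days. Which dye held which pool was taken from the labels.

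The deposited scanner files hold the mean intensity of each spot and the median intensity of its local background in both channels, as written by Agilent Feature Extraction, per the file headers. They also hold a log10 ratio of Cy5 over Cy3, after the software's own background subtraction and dye normalization, per the file headers. The authors' deposited series table holds a log10 ratio with 1 value per feature. That table equalled the scanner files' log10 ratio, turned to the first-named over the second-named pool, within 1e-06 for 97.9% of features in the deposited data, and for 100% of features whose probe has a single spot. Its scale, direction and lack of further centring were thus found from the values, and nothing about these stayed unknown for single-spot probes. Its medians per array, as log10 with the array of the first-named pool in Cy5 before its dye swap, were 0.0301 and 0.00252 on day 3 of FVB/N abraded over sham. They were 0.0113 and 0.00335 on day 5, -0.00135 and -0.00386 on day 9, -0.000541 and -0.00067 on day 18, and 0 and -0.000735 on day 30. For Tg.AC over FVB/N they were 0.0196 and 0.00163, 0.00239 and -0.00452, 0 and -0.000609, 0 and 0, and 0.0061 and -0.00306 on the 5 days.

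Each array held 22393 features, of which 1075 were controls. Intensities were background-corrected by normexp with an offset of 50 and normalized within each array by loess, in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Control spots and spots that the files mark as outliers were then left out, and saturated spots were kept. Spots of 1 probe were averaged, which left 20868 probes. Of these, 8947 were named through an accession in the gene table given, 522 through a symbol or synonym, and 380 kept the symbol of the file. The remaining 11019 kept their accession or probe identifier and are counted but not named. The rule for synonyms was made stricter after values had been seen. For 19 probes the accession and the printed symbol name different current genes. For each gene the probe brightest over all arrays was used, which gave 20745 genes or accessions, 9737 with a symbol. A second probe of Mylpf, Myh2, Nos3, Gsr, Gstm5, Spred2, Tgm3 or Dst gave another sign or size. A probe was tested where at least 5 of the 20 channels of a comparison lay well above background by the files' own mark. This left 20133 genes or accessions for FVB/N abraded over sham and 20591 for Tg.AC over FVB/N.

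Median intensity per channel ranged from 104 to 373 over a background of 57.5 to 69 in the first comparison, and from 377 to 913 over a background of 283 to 320 in the second. Ratios were turned to the first-named over the second-named pool, and the 2 arrays of a day were averaged as 1 replicate. Limma's lmFit and eBayes were fitted to the 5 day averages of each comparison, with an intercept and a centred slope on log2(day), at a Benjamini-Hochberg adjusted p under 0.05. The p-values and SEs thus measure the spread of the pool pairs of different days around that slope, as moderated by eBayes. They do not measure the spread between animals. On single days a gene was counted at a log2 ratio of at least 1 with the same sign on both arrays, with no test. A pool in which a probe was not well above background on either array of a day has only a bound. That fold is the brighter pool's mean against the higher of the lowest signal well above background and the dim probe's own, per channel after loess and Aquantile scaling.

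For 30 gene lists limma's camera was run with a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Counts in a list were taken over all genes tested and also adjusted over the list alone. The median of a list on a day was set against 10000 random lists of the same size matched on intensity. The relation of the comparisons was simulated 100 times from unchanged groups that share the FVB/N abraded pools.

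Genes were named by rule. Of those passing for the mean with the same sign on all 10 arrays, the 8 highest and 8 lowest means were named, or the 5 largest of the same sign where fewer than 5 passed. On each day the 3 highest and 3 lowest of the counted genes were named, and of each list up to 4 members with the largest values. Hras, Hba-x, Lor, S100a8 and Ptgs2 were named in any case; Krt6a, Krt10, Krt14 and Mki67 belonged to this group but had no probe that could be named. Csnk1g2, F2r and Olfr114 in Tg.AC over FVB/N were looked at after their values were seen. The grouping, tests, lists, naming rule and first alternatives were fixed before the data were examined. These alternatives covered background correction, normalization, filters, probes, dye orientation, model, size rule, list test and left-out days. Removal of the probe dye effect, a dye term, and leaving out days 5 and 9 or 1 array of day 18 were added after the data had been seen.

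The steps were tested on simulated data. With 200 genes changed on the spread of FVB/N abraded over sham (20133 genes), 91.5%, 97% and 100% were recovered for mean log2 changes of 1, 2 and 4, and 92.5%, 98% and 100% for slopes. On the spread of Tg.AC over FVB/N (20591 genes) the shares were 91.5%, 99.5% and 99.5% for means and 96%, 98% and 100% for slopes. Between 6 and 18 unchanged genes were called. Of the 30 lists the shifted list was called and 0 others. The simulated genes were drawn independently, so this does not test camera's preset correlation where the genes of a list move together. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.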

Results

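Gene expression in mouse dorsal skin was followed after light wounding of the epidermis. The skin was shaved, depilated and abraded with a felt wheel, and sham animals went through the same steps without abrasion. Tg.AC mice are FVB/N mice that carry a v-Ha-ras transgene behind a zeta-globin promoter, and they form papillomas where the skin has been wounded. Skin was taken at 5 times, days 3, 5, 9, 18 and also 30, and total RNA of 5 female mice was pooled for each group and day. One comparison set abraded FVB/N skin against sham FVB/N skin, which asks what abrasion does to skin without the transgene. The other set abraded Tg.AC skin against abraded FVB/N skin, which asks how the papilloma-prone strain differs after the same wound. Arrays with sham Tg.AC skin were not analysed here, so a strain difference cannot be parted from a difference in the response to abrasion. Each pair of pools was hybridised on 2 two-colour arrays with the dyes swapped, which gave 10 arrays per comparison and 20 in all. Between 76.2% and 98.7% of features per channel lay well above background in the first comparison, and between 81.9% and 99.6% in the second. The number of pools, 1 per group and day, limits the precision.

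Once turned to the same direction, the opposing arrays of FVB/N abraded over sham correlated across probes at 0.80, 0.76, 0.62, 0.45 and 0.78, from day 3 to day 30 in turn. The opposing arrays of Tg.AC over FVB/N correlated at -0.07, -0.61, -0.41, 0.37 and 0.67 on the same days. Genes and probes are not independent replicates, so these values only describe the arrays.

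Hras, the mouse counterpart of the v-Ha-ras gene in the transgene, was examined first. Whether its probe detects the transcript of the transgene was not tested. Abraded Tg.AC skin lay above abraded FVB/N skin by log2 0.07, 0.28, 0.32 and 0.45 on days 3, 5, 9 and 18, and by 3.54 on day 30, with 3.38 and 3.70 on its 2 arrays. The arrays of days 3, 5 and 9 differed in sign, so Hras stood apart on both arrays only on days 18 and 30. The mean over the days was 0.93 ± 0.39 (SE, n = 5) and did not pass in limma (adjusted p = 0.804). In FVB/N skin without the transgene, abrasion raised Hras by 0.55 ± 0.09 (SE, n = 5; adjusted p = 0.0271), on 10 of 10 arrays. The probe of Hba-x, the embryonic globin gene whose promoter drives the transgene, had Tg.AC over FVB/N values between -0.19 and 0.09, and on day 9 it was not well above background on either array.

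Over the 5 days of FVB/N abraded over sham, limma's camera called genes of wound-activated keratinocytes higher and genes of lipid synthesis and of mitochondrial respiration lower. With an estimated correlation the adjusted p was 0.588, 0.721 and 0.797, so camera's calls rest on the preset one. Fry, which does not use it, gave adjusted p of 0.0165, 0.0188 and 0.0972 for these 3 lists. Of the genes for small proline-rich proteins, which are cross-linked into the cornified envelope, Sprr2d rose by a mean log2 of 3.91 ± 0.50, Sprr1b by 3.91 ± 0.26 and Sprr2a1 by 3.74 ± 0.22 (SE, n = 5), while Sprr1a, Sprr2h, Sprr3 and Sprr4 did not pass. The calprotectin subunits S100a8 and S100a9 rose by means of 3.89 ± 0.44 and 4.34 ± 0.47, and S100a9 reached 6.71 on day 3. Hamp, which encodes the iron hormone hepcidin, fell by 3.23 ± 0.35 (mean log2 over the days, SE, n = 5), and Ccl27a, a chemokine of keratinocytes, fell by 2.63 ± 0.24.

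Limma called 2181 genes higher and 2749 lower among 20133 tested genes or accessions, with n = 5 pool pairs. Of these, 1046 higher and 1652 lower genes had the same sign on all 10 arrays. Of the calls 44.2% were higher, and with median centring in place of loess 57.4% were. The share was 87.0% with no trend term in the model, 81.5% with the trend taken on the day itself and 93.9% without day 5, each of far fewer calls. The lowest adjusted p was 0.0200, and the count rested on single days: limma called 0 genes without day 3 (5434 at unadjusted p under 0.05), 33 without day 5 and 0 without day 18 (7517 unadjusted). The count was 292 with no trend term in the model, 184 with the trend taken on the day itself and 7594 over the 10 arrays with the day as a random block and a dye term. That last fit takes the technical dye-swap arrays of a day as partly separate, so its count does not rest on the 5 pool pairs alone.

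Of the genes with the same sign on all arrays, the highest means also included Mrm2 at 3.96 ± 0.23, Plxnb3 at 3.90 ± 0.21 and Stfa3, a stefin that inhibits cysteine proteases, at 3.88 ± 0.39 (SE, n = 5). The probes of Mrm2 and Plxnb3 are named by their accessions, and it is unsure whether they measure these genes in skin; the same holds for Kcng4 and Olfr114 below. Hsd11b1, which makes active glucocorticoid in skin, rose by 3.34 ± 0.34, and Il6ra, the interleukin-6 receptor subunit, rose by 3.20 ± 0.26. The lowest means also included Retnla, a marker of alternatively activated macrophages, which fell by 2.91 ± 0.60, and Cyp2f2, which fell by 2.57 ± 0.33. The fat cell products Cfd and Adipoq fell by 2.30 ± 0.24 and 2.05 ± 0.24. Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 2.15 ± 0.24, and the fatty acid elongase Elovl5 fell by 1.99 ± 0.24. Ptgs2, which encodes cyclooxygenase-2, rose by a mean of 0.80 ± 0.16 (adjusted p = 0.0341), from 2.31 on day 3 to 0.03 on day 30 as single values. Lor, the main protein of the cornified envelope, had a mean of -0.88 ± 0.69 (adjusted p = 0.369), with -4.28 on day 3 and 2.03 on day 18.

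Of 24 measured wound-activated keratinocyte genes, 14 rose, 0 fell and 10 did not pass; adjusted over the list alone, 19 rose and 1 fell. Limma's camera called the list higher (adjusted p = 1.17e-06), and the adjusted p was 0.588 with an estimated correlation. Of 41 neutrophil and acute inflammation genes, S100a8 and S100a9 of the wound-activated list among them, 14 rose and 1 fell, with 22 and 1 adjusted over the list alone. Cxcl5, a neutrophil chemokine, rose by a mean of 2.02 ± 0.26 and the acute phase protein Saa1 by 1.94 ± 0.20 (SE, n = 5). Of 39 macrophage genes, 17 rose and 2 fell, with 19 and 3 adjusted over the list alone. Lyz2 rose by 2.09 ± 0.22, Cd14 by 1.16 ± 0.10 and Arg1 by 1.17 ± 0.28, while Retnla of the same list fell. Of 9 B cell genes, 2 rose and 0 fell, with 6 and 0 adjusted over the list alone. These 3 lists were called higher by camera (adjusted p = 8.81e-06, 0.00202 and 0.0264). With an estimated correlation the adjusted p was 0.721, 0.588 and 0.721. Camera did not call the B cell list without day 3 (adjusted p = 0.0753), without day 5 (adjusted p = 0.0546) or on the dye-swap arrays alone (adjusted p = 0.248).

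Of 33 collagen and granulation matrix genes, 12 rose and 1 fell, with 13 and 3 adjusted over the list alone. Tnc, the wound matrix protein tenascin C, rose by a mean of 1.96 ± 0.26, Col5a2 by 1.30 ± 0.25 and Timp1 by 1.13 ± 0.19 (SE, n = 5), while Ccn2 fell, with -2.33 on day 3. Timp1 was not well above background in sham skin on days 3 and 5, where abraded skin was at least 6.95-fold and 2.47-fold higher. Of 31 matrix protease and plasminogen genes, 9 rose and 1 fell, with 11 and 2 adjusted over the list alone. Klk6 rose by 2.00 ± 0.23, Mmp3 by 1.24 ± 0.07 and Mmp13 by 1.07 ± 0.15. Of 28 skin papilloma marker genes, 10 rose and 0 fell, with 15 and 0 adjusted over the list alone, and Gjb6, a gap junction protein, rose by 1.18 ± 0.14. Tnc, Klk6 and Mmp13 belong to the papilloma list too, and Klk6 also to the wound-activated list, so these lists are not separate. Camera called the collagen, protease and papilloma lists higher (adjusted p = 0.0457, 0.00524 and 0.00084). With an estimated correlation the adjusted p was 0.797, 0.721 and 0.588. Camera did not call the collagen list without day 9 (adjusted p = 0.154), without day 18 (adjusted p = 0.202) or on the arrays with abraded skin in Cy5 alone (adjusted p = 0.352).

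Of 22 sebaceous gland and lipid synthesis genes, 12 fell and 1 rose, with the same numbers adjusted over the list alone. Among those that fell, Cidea had a mean log2 ratio of -1.87 ± 0.17, Elovl6 of -1.71 ± 0.12 and Apoc1 of -1.49 ± 0.28 (SE, n = 5). Of 44 mitochondrial respiration genes, 26 fell and 5 rose, with 35 and 5 adjusted over the list alone; Ndufa5 fell by 1.22 ± 0.25 and Ndufb3 by 1.16 ± 0.22. Markers of skeletal muscle, a tissue rich in mitochondria, fell in part as well (12 of 38), and whether a lower share of muscle in the pools plays a part was not tested. The ribosomal protein genes stood low on the same early days, with medians of -0.78 on day 3 and -1.45 on day 5, against -1.57 and -1.34 for the mitochondrial genes. Camera called both lists lower (adjusted p = 1.17e-06 and 3.8e-07). With an estimated correlation the adjusted p was 0.721 and 0.797. Fry, which asks whether the genes of a list move one way on balance, called 8 lists for the mean, among them neither the collagen nor the mitochondrial list (adjusted p = 0.0972 for both).

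Genes of 7 further lists passed where camera did not call the list for the mean. Of 38 skeletal muscle genes, 12 fell and 2 rose, with 14 and 3 adjusted over the list alone; Mstn fell by 2.19 ± 0.26 and Tnni2 by 2.18 ± 0.30. Of 22 adipocyte genes, 6 fell and 3 rose, with 7 and 3 adjusted over the list alone, and Fabp4 fell, with -1.52 on day 3 and -1.33 on day 30. Of 21 cornified layer genes, 4 rose and 0 fell, the same adjusted over the list alone, with Casp14 at 1.95 ± 0.34 and Dsc1 at 1.55 ± 0.20. Of 37 Ras and EGF receptor response genes, 8 rose and 3 fell, with 10 and 4 adjusted over the list alone, and fry called this list higher (adjusted p = 0.0398). Of 30 glutathione and oxidative stress genes, 7 rose and 9 fell, with 9 and 9 adjusted over the list alone. Of 36 Wnt and hedgehog genes, 6 rose and 8 fell, with 7 and 9 adjusted over the list alone, and the Wnt target Axin2 rose by 1.64 ± 0.25. Of 32 ribosomal protein genes, 7 rose and 6 fell, with 8 and 12 adjusted over the list alone.

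Of 44 cell cycle genes, 5 rose and 5 fell, and of 31 T and NK cell genes, 4 rose and 4 fell, with 5 and 5 for either list adjusted over the list alone. Of 35 hair shaft and inner root sheath genes, 4 rose, and 0 did so adjusted over the list alone. Of 15 mast cell genes, 5 rose and 1 fell, and of 31 endothelial genes, 5 rose and 1 fell, with the same numbers adjusted over the list alone. Of 17 antigen presentation and Langerhans cell genes, 3 rose and 3 fell, with 4 and 3 adjusted over the list alone. Of 19 hypoxia and glycolysis genes, 4 rose and 2 fell, and of 10 basal keratinocyte genes, 2 rose and 2 fell, with the same numbers adjusted over the list alone. Of 8 smooth muscle genes, 2 rose and 0 fell, with 2 and 1 adjusted over the list alone. Of 11 nerve genes 3 fell, of 15 hair follicle bulge genes 2 fell, of 12 melanocyte genes 1 fell and of 9 red blood cell genes 1 rose, each the same adjusted over the list alone. Of 31 interferon response genes, 1 rose, and 0 did so adjusted over the list alone. Camera called 9 of the 30 lists for the mean, and these 14 and the 7 lists led by skeletal muscle had adjusted p between 0.142 and 0.989.

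No gene passed limma for a trend over the 5 days of FVB/N abraded over sham (0 rising, 0 falling, 5415 at unadjusted p under 0.05). Limma called 10 with trended, robust variances and 3215 over the 10 arrays with the day as a random block and a dye term. The latter fit takes technical dye-swap arrays as partly separate, so its count does not rest on the pool pairs alone. Camera called 11 lists for the trend, 0 with an estimated correlation (adjusted p of at least 0.644) and 0 by fry. The steepest fall was that of the neutrophil and acute inflammation genes, with medians of 1.31, 0.52, 0.26, 0.08 and -0.03 on the 5 days (camera adjusted p = 7.79e-12; adjusted p = 0.644 with an estimated correlation). Adjusted over the list alone, 21 of them fell with time. The cornified layer genes had medians of -0.71, -0.26, 1.14, 1.94 and 0.61 (camera adjusted p = 0.0116; adjusted p = 0.722 with an estimated correlation). The hair shaft and inner root sheath genes had medians of 0.42, -1.56, -0.92, -0.25 and 1.82, and their trend was not called (adjusted p = 0.43).

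**Figure D1:**
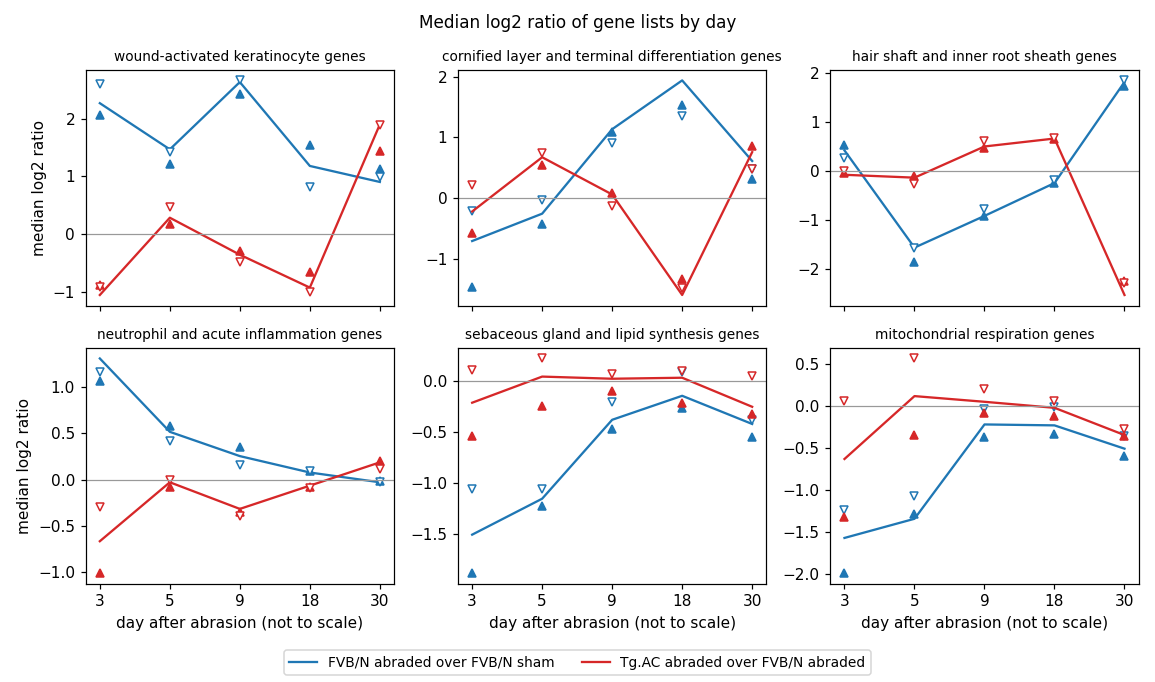
Median log2 ratio (y axis) of 6 gene lists on each day (x axis, days not spaced to scale), for FVB/N abraded over sham (blue) and Tg.AC abraded over FVB/N abraded (red); lines join medians of the dye-swap averages, filled and open triangles are the medians on the array with the first-named pool in Cy5 and on the dye-swap array. The wound-activated keratinocyte median in blue stays above 0 on all days, and in red it goes from -0.93 on day 18 to 1.90 on day 30, where the hair median reaches -2.53.

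On single days, with 1 pool per group and no test, 507 genes were at least 2-fold higher and 1873 at least 2-fold lower on both arrays on day 3, and 696 and 941 on day 5. The counts were 197 and 130 on day 9, 157 and 22 on day 18, and 540 and 114 on day 30. On day 3 the median intensity before normalization was higher for abraded than for sham skin on both arrays (245 against 167, and 373 against 104). On the other days Cy3 was the brighter channel on both arrays. Whether this difference in signal plays a part in the excess of lower genes on day 3 was not tested. With the spread of the arrays made equal, the first 4 days had 479, 483, 597 and 538 genes in all. That scaling evens out the spread of the days by construction, so these counts cannot decide whether the early excess is real. On day 3 S100a9, S100a8 and Mrm2 were highest (6.71, 6.29 and 4.89) and Retnla, Hamp and Ccl27a lowest (-6.68, -5.18 and -4.94). On day 5 Sprr2d, Sprr1b and Sprr2a1 were highest (4.39, 3.96 and 3.95), and the hair genes Krtap15, Krtap21-1 and Krt33a were lowest (-7.12, -5.81 and -5.78). On day 9 a cysteine protease inhibitor probe that the files name MS2 was highest with S100a9 and Sprr2d (5.55, 5.48 and 5.18), and Krtap6-2, Krt33a and Krtap28-13 were lowest (-2.44, -2.43 and -2.42). On day 18 Krt1, the keratin of differentiating epidermis, was highest with Stfa3 and Sprr2d (4.99, 4.94 and 4.52), and Hamp, Cyp2f2 and Ccl27a were lowest (-2.66, -1.48 and -1.43). On day 30 Csnk1g2, F2r and the probe named Olfr114 were highest (4.67, 4.49 and 4.36), and Hamp, Retnla and Adipoq were lowest (-2.86, -2.20 and -2.14).

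By genes at least 2-fold apart on both arrays, abraded Tg.AC and FVB/N skin differed most on day 30, with 559, while on the arrays with Tg.AC in Cy5 alone day 3 had 1691 and day 30 had 1004. On day 30 its wound-activated keratinocyte genes lay above those of FVB/N by a median of log2 1.90, with 1.45 and 1.90 on the 2 arrays, and its hair shaft and inner root sheath genes lay below by a median of -2.53. On day 18 it lay below FVB/N in the wound-activated genes (-0.93) and in the cornified layer genes (-1.60). These are values of 1 pool per strain and day, and no day was tested.

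Over the 5 days no gene passed limma for the mean (0 higher and 0 lower of 20591 tested; 711 at unadjusted p under 0.05) or for the trend (0 rising, 0 falling; 997 unadjusted). Limma on 10 arrays with the day as a random block and a dye term, and limma with trended, robust variances, also called 0 for both. On the arrays with Tg.AC in Cy5 alone, where the dye does not cancel, limma called 439 for the mean. Only 4 genes were higher and 38 lower on all 10 arrays. In all this is about as many as independent random signs would give among 20591 genes. Such signs would split evenly, however, and the paired arrays of days 5 and 9 correlated at -0.61 and -0.41. The total therefore cannot tell whether the 38 lower genes arose by chance, and the uneven split was not tested. Of those with a symbol, the higher ones, Saa4 and Sprr3, had means of 0.17 and 0.13. The lowest means were those of Matn2 (-0.55 ± 0.14), Serpinf1 (-0.52 ± 0.06), Aqp1 (-0.52 ± 0.10), Pdgfra, a receptor of fibroblasts (-0.49 ± 0.09), and Cd302 (-0.49 ± 0.11; SE, n = 5), each with an adjusted p of 0.804.

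Camera called 4 lists lower over the days of Tg.AC over FVB/N, each by a small median. They were the neutrophil and acute inflammation genes (-0.16, adjusted p = 3.44e-07), the collagen and granulation matrix genes (-0.12, adjusted p = 2.67e-05), the mitochondrial respiration genes (-0.18, adjusted p = 1.78e-05) and the macrophage genes (-0.08, adjusted p = 8.87e-05). With an estimated correlation the adjusted p was 0.937 for each of the 4, and by fry it was 0.975. On the arrays with Tg.AC in Cy5 alone camera called all 4 lower, with medians of -0.27, -0.40, -0.43 and -0.31 in the same order. On the dye-swap arrays alone the mitochondrial list was called higher (0.08, adjusted p = 0.0203), and the neutrophil, collagen and macrophage lists were not called (-0.06, 0.04 and 0.005). Without day 3 the medians of the neutrophil, mitochondrial and macrophage genes were -0.06, -0.04 and -0.01. Without day 30 those of the neutrophil, collagen and macrophage genes were -0.27, -0.25 and -0.16. The neutrophil median was -0.09 without day 9, and the macrophage median -0.14 without day 5. No member of any of them passed over all genes, and adjusted over the list alone 2 of 34 collagen genes were lower. Each of the other 26 lists also had 0 passing genes, and among them adjusted over the list alone 1 of 40 skeletal muscle genes was lower. Camera did not call these 26 for the mean, with adjusted p between 0.158 and 0.973. Camera called 8 lists for the mean without day 3, 7 without day 5, 7 without day 9 and 12 without day 30.

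For the trend camera called 13 lists of Tg.AC over FVB/N, and 0 with an estimated correlation (adjusted p of at least 0.704) or by fry (adjusted p of at least 0.616). The cell cycle genes rose relative to other genes with time (adjusted p = 8.05e-13; adjusted p = 0.704 with an estimated correlation), from a median of -0.24 on day 3 to 0.21 on day 30. The neutrophil genes had medians of -0.67 and 0.19 on those days (adjusted p = 1.41e-07; adjusted p = 0.704 with an estimated correlation). Without day 30 camera called 5 lists for the trend. The trends of the hair and wound-activated lists then turned, with median slopes from -0.50 to 0.36 and from 0.35 to -0.16.

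**Figure D2:**
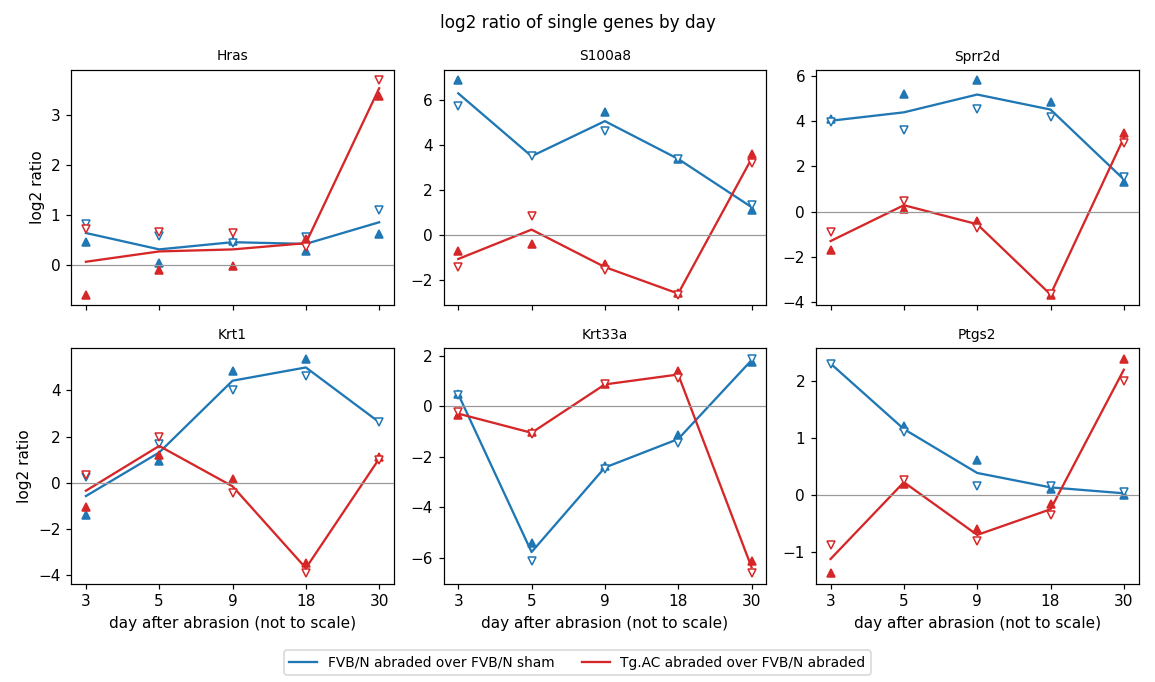
log2 ratio (y axis) of 6 genes on each day (x axis, days not spaced to scale), for FVB/N abraded over sham (blue) and Tg.AC abraded over FVB/N abraded (red); lines join dye-swap averages, filled and open triangles are the array with the first-named pool in Cy5 and the dye-swap array. In red, Hras stays between 0.07 and 0.45 up to day 18 and reaches 3.54 on day 30, and S100a8 goes from -2.60 on day 18 to 3.38 on day 30.

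On day 30, 183 genes were at least 2-fold higher in Tg.AC and 376 at least 2-fold lower on both arrays. Hsd11b1, Gsta1 and the probe named Kcng4 were highest (5.02, 5.01 and 4.91), and the hair genes Krtap15, Krtap14 and Krt33a were lowest (-7.46, -7.04 and -6.37). Of the wound-activated genes Sprr1b stood at 4.86, Sprr2e at 4.06 and S100a9 at 3.79, and S100a8 at 3.38. Of the papilloma markers, with a median of 0.38, Ptgs2 stood at 2.20, Gjb6 at 2.29 and Odc1, the ornithine decarboxylase of polyamine synthesis, at 1.98. The hypoxia and glycolysis genes had a median of 0.46, with Tpi1 at 1.48 and Slc16a3 at 1.18. The Ras and EGF receptor response genes had a median of 0.21 and the cell cycle genes of 0.21, with Mcm5 at 1.03. Each of these 5 medians, wound-activated genes included, lay above all 10000 random lists matched on intensity, and the hair median lay below all of them. The cornified layer (0.76), basal keratinocyte (0.63, but 0.09 on the array with Tg.AC in Cy5) and neutrophil (0.19) medians also lay above all random lists, and the mitochondrial median (-0.35) below all. Random lists hold genes drawn singly, while genes of a list can move together, so these placings are no test. Nor are the lists separate, since Ptgs2 and Odc1 stand in both the papilloma and the Ras list.

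On day 18, 17 genes were at least 2-fold higher in Tg.AC and 113 at least 2-fold lower. Krt1, Sprr2d and the MS2 probe were lowest (-3.69, -3.66 and -3.12), followed in their lists by S100a9 (-3.02), Rptn (-3.02) and S100a8 (-2.60), and Lor stood at -1.68. Krtap4-2, Krtap6-1 and Krtap15 were highest (1.43, 1.43 and 1.42). Across genes the ratios of day 18 and day 30 correlated at -0.56, and the direction of each was kept because the labels give the dyes. The array of day 18 with Tg.AC in Cy5 was extracted on another date than the other 9 arrays of the comparison. The dye-swap array alone gave a median of -1.48 for the cornified layer genes.

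On the early days fewer genes stood apart on both arrays. On day 3 there were 3 higher and 69 lower, with Mup1 at 1.21, the neutrophil granule gene Ngp at -2.03, Krt71 at -2.02 and Serpinb2, a plasminogen activator inhibitor, at -1.88. On day 5 there were 5 higher and 14 lower. Spp1, which encodes osteopontin, and the macrophage chemokines Ccl3 and Ccl4 were highest (2.31, 2.26 and 2.21), and Krtap21-1, Krt71 and Cxcl5 were lowest (-2.93, -2.53 and -1.86). On day 9 there were 3 higher and 7 lower, with the hair keratins Krt25 and Krt35 and Fbp1 highest (1.54, 1.31 and 1.26). Cxcl5, Spp1 and Saa1 were lowest on day 9 (-3.77, -2.11 and -1.97).

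The genes that abrasion of FVB/N skin had moved at least 2-fold on day 3 were followed into the strain comparison. The 506 genes that had been higher lay above FVB/N in Tg.AC skin on day 30 by a median of 0.44, with 80.7% of them above 0 on both arrays, against a range of -0.08 to 0.11 for 10000 random lists. The 1872 genes that had been lower lay below by a median of -0.42, with 79.5% of them below 0 on both arrays, against -0.02 to 0.06. On days 3, 5 and 9 the medians were 0.05, 0.02 and -0.17 for the higher genes, and -0.44, 0.01 and 0.00 for the lower genes. The higher genes lay above all random lists on day 3 (-0.27 to 0.00) and below all on day 5 (0.05 to 0.12) and day 9 (-0.02 to 0.05). The lower genes lay below all on day 3 (-0.15 to -0.03) and day 5 (0.04 to 0.07). The 2 arrays differed in sign for the higher genes on day 3 (-0.07 and 0.36) and the lower genes on day 5 (-0.16 and 0.17). Those averages therefore give no direction between the strains. The genes were picked on day 3 in a ratio that holds the FVB/N abraded pool, which biases the strain ratio of that day if the pool is the same. On day 18 the higher genes had a median of 0.15, with 0.22 and 0.009 on the 2 arrays (random lists -0.05 to 0.04). The lower genes had a median of 0.01 on that day (random lists -0.03 to 0.02). With the spread of the arrays made equal, the genes were picked again from those values, where day 3 had 479 genes in both directions. The higher genes of that other set had medians of -0.70 on day 18 and 1.23 on day 30. Without background correction, with genes again picked from those values, the day 30 median of the lower genes was -0.28.

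Across 20093 genes the mean log2 ratios of both comparisons correlated at 0.56, with a covariance of 0.033. Both comparisons use abraded FVB/N pools of the same description with opposite sign, and whether these are the same pools is not given in the sources used here. If they are, unchanged groups gave a simulated correlation of -0.32 ± 0.03 (SD) and a covariance of -0.008. Without day 30 the observed correlation was 0.10.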

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

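All tests in this part were chosen after the result or closely related values had been seen, except the share of kept signs used for exchanged labels. A day stood apart from the other 4 in 4 of 69 groups of 5 days looked at, and chance gives about 1 in 20. The gap ratio had to pass 0.71. In Tg.AC over FVB/N, Hras stood at 3.54 on day 30, against 0.07 to 0.45 on the other days. The hair shaft and inner root sheath median there stood at -2.53 on day 30, against -0.13 to 0.66. The melanocyte median stood at -0.31 on day 30, against 0.02 to 0.14. In FVB/N abraded over sham the melanocyte median stood at 0.20 on day 30, against -0.11 to -0.04.

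In 4 cases the median of a list lay above 0.5 on both arrays of 1 day and below -0.5 on both arrays of another. These differences were not tested, and the size of 0.5 used to pick them was set after seeing the values. The hair median of FVB/N abraded over sham was 1.82 on day 30 and -1.56 on day 5. In Tg.AC over FVB/N the wound-activated keratinocyte median was 1.90 on day 30 and -1.06 on day 3. The cornified layer median was 0.67 on day 5 and -1.60 on day 18, and the hair median was 0.66 on day 18 and -2.53 on day 30.

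On day 18 abraded Tg.AC skin lay below abraded FVB/N skin in wound-activated and cornified layer genes. The 110 genes at least 2-fold lower in Tg.AC had medians in FVB/N abraded over sham of 0.16, 0.64, 2.34, 2.40 and 0.86 on the 5 days. The day 30 value, in other animals, lay above all random lists (-0.20 to 0.18), so a high level was not limited to the day 18 pool. Whether that pool was unusually high cannot be told, because the genes were picked by a ratio over abraded FVB/N skin. A candidate explanation is that these genes had returned to near the sham level in Tg.AC skin. With both comparisons added, which holds only if the abraded FVB/N pool is the same in both, their median over sham was 0.45, against 2.40 for FVB/N. The summed median was 2.08 on day 9 and 2.56 on day 30, so such a return would need a renewed rise. Picking the genes for low values on day 18 biases that day's sum downward and, if the pool is shared, the 2.40 upward. Exchanged strain labels stay open. Of 112 genes with 1 sign on the other 8 arrays, 52.7% kept it on day 18 (95% exact binomial interval 43.0 to 62.2%, and genes are not independent). That set is no larger than independent random signs would give among 20591 tested genes. The 2 arrays of a day are not independent, so that number is only a rough guide. The share cannot decide. Hras, 1 gene, at 0.53 and 0.36 on the 2 arrays of day 18, runs as the labels say, if its probe detects the transgene.

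Hair genes moved together on single days of both comparisons. Cross-hybridisation among keratin and keratin-associated probes is argued against, since the 14 list members of other kinds had a median of -1.02 on day 30 of Tg.AC over FVB/N (random lists -0.31 to 0.33). Among these 14, Dlx3, Lef1, Fgf5, Msx1 and Foxn1 stood near 0 or above (-0.005, 0.03, 0.13, 0.27 and 0.29), and the rest at -0.51 or lower. A different share of growing hair follicles in the pools stays open: the melanocyte median had the sign of the hair median on 6 of 6 days where the latter passed 0.5, a size set after the values were seen. On day 3 of both comparisons and day 5 of Tg.AC over FVB/N, under that size, the signs were opposite, and on days 5 and 9 of FVB/N abraded over sham the melanocyte medians of the 2 arrays differed in sign. These days are not independent if the FVB/N abraded pools are shared, because that pool stands in both ratios of a day. Whether strain or abrasion shifts the hair cycle was not tested.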

How the results depend on the processing

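The alternatives that removed a dye effect, added a dye term or left out days 5 and 9 or 1 array of day 18 were chosen after the data had been seen. No paired analysis was possible because the groups on an array are compared within it and the days hold separate pools. A slide or date block was not run: each array is its own slide, the first comparison has 1 extraction date, and the other has 9 arrays on 1 date and 1 array on another. No date is shared between the comparisons, so date and comparison cannot be told apart. Medians of the early genes rest on single days, so leaving out a day gives no value for them. Of the named genes of FVB/N abraded over sham, 244 values under alternatives kept direction and call and 75 kept direction but lost the call. Of list values 549 kept both, 66 lost the call and 11 turned. Of the mean counts in 1 direction 68 stayed within 1.5 times and 16 did not, and of the day counts in 1 direction 61 and 49. The lowest share of features well above background in a channel was 76.2% in the first comparison and 81.9% in the other. Except where a rule is stricter or looser by its construction, the cause was not tested.

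The count of genes for the mean of FVB/N abraded over sham (4930) ranged from 0 to 5584 with 1 day left out (0 without day 3 or 18, 33 without day 5). It was 292 with an intercept alone, 184 with the trend on day itself and 7594 with a random block. The trend count (0) was 10 with trended, robust variances and 3215 with a random block. Both random-block counts lean on technical dye-swap arrays beside the pool pairs. For Tg.AC over FVB/N the mean count (0) was 439 with the first-named pool in Cy5 only. With 1 day left out, the lists called for the mean there (4) ranged from 6 to 12 and for the trend (13) from 5 to 17.

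Lists called in FVB/N abraded over sham (9 for the mean, 11 for the trend) fell to 0 and 0 with an estimated correlation. By fry they fell to 0 for the trend, while fry still called lists for the mean. The trend lists were 7 with median centring, 5 with scaling between arrays and 7 with Cy5-first arrays only. In Tg.AC over FVB/N both were 0 with an estimated correlation and by fry, and the mean lists were 7 with Cy5-first arrays, 2 with dye-swap arrays and 7 without days 5 and 9. Direction here is camera's and the values are list medians. With dye-swap arrays only, the direction turned for the macrophage mean (0.004791) and trend (-0.02834), the mitochondrial mean (0.07722), and the matrix protease (1.716e-05) and ribosomal (-0.004472) trends. Without day 3 the ribosomal trend turned (-0.1132). Without day 30 the trends of wound-activated (-0.1608), hair (0.3611), papilloma (-0.0357), skeletal muscle (0.02808) and interferon genes (-0.03971) turned. With 1 day left out the wound-activated trend reached up to 0.6367, the papilloma trend 0.191, the interferon trend 0.08077 and the ribosomal trend 0.2775. The hair and skeletal muscle trends reached down to -0.7848 and -0.1212.

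Genes 2-fold apart in FVB/N abraded over sham numbered 2380, 1637, 327, 179 and 654, from day 3 to day 30 in turn. With Feature Extraction's ratio, and the series table alike, they numbered 3964, 3110, 643, 347 and 1197. Scaling between arrays gave 479, 483, 597 and 538 on the first 4 days. Cy5-first arrays gave 4956, 3977, 611 and 270 on these, and dye-swap arrays 2628, 770, 932 and 1205 on the last 4. A 3-fold rule gave 793, 422, 158, 78 and 276, and the mean of both arrays 3659, 2917, 541 and 434 on the first 4 days. Limma with the spread between dye-swap arrays as error, for these pools only, gave 7166, 6664, 759, 578 and 1907, and with a dye term 10210, 9686, 1946, 1353 and 3829. With the probe dye effect taken off, day 18 gave 307.

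In Tg.AC over FVB/N they numbered 72, 19, 10, 130 and 559. No background correction gave 30, 8, 5, 78 and 315. Feature Extraction's ratio, and the series table alike, gave 29, 26 and 846 on days 5, 9 and 30. Median centring gave 31 and 16 on days 3 and 9, and scaling 4, 51 and 217 on days 3, 9 and 18. Cy5-first arrays gave 1691, 390, 107, 354 and 1004, and dye-swap arrays 662, 474, 417, 201 and 1349. A 3-fold rule gave 4, 8, 2, 50 and 288, and the mean of both arrays 259, 48, 51, 202 and 937. Limma on technical error gave 779, 11 and 1799 on days 3, 5 and 30, and with a dye term 2872, 105, 414 and 3425 on days 3, 9, 18 and 30. Without the probe dye effect day 9 gave 21, and without the array of another date day 18 gave 201.

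The relation across genes (0.56) ranged from 0.09863 without day 30 to 0.6005 without day 18, with 0.5191 without day 3 and 0.3978 without day 5. It was 0.5354 without background correction, 0.6094 with median centring, 0.3807 with scaling, 0.6077 with Cy5-first and 0.5909 with dye-swap arrays. With scaling, and without background correction, the early genes were picked again from those values. The early higher genes on day 18 (0.15) stood at -0.6999 with scaling, a reversal in another set of genes, and at 0.008617 with dye-swap arrays. On day 30 (0.44) they stood at 1.234 with scaling and 0.5478 with Cy5-first arrays. The early lower genes on day 18 (0.01) stood at 0.09365 with genes from day 5, 0.05218 with genes from both days and 0.04924 with Cy5-first arrays. On day 30 (-0.42) they stood at -0.6178, -0.539, -0.2757 without background correction, -0.4942 with dye-swap arrays and -0.5071 with scaling, the first 2 again with genes from day 5 and from both days.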

Other observations

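The tests of the dye pattern, of the trends and of the Tg.AC mean in this part were chosen after the result or closely related values had been seen. Several genes high in FVB/N skin 30 days after abrasion were low on that day in Tg.AC over FVB/N. Csnk1g2 stood at 4.67 over sham and at -4.41 in the strain ratio, F2r at 4.49 and -2.36, and the probe named Olfr114 at 4.36 and -3.08. The hair median went the same way (1.82 and -2.53), and so did melanocyte genes, with Pmel, a pigment granule protein, at 1.61 and -1.30 and Dct at 1.02 and -2.57. The abraded FVB/N pool of day 30 stands in both ratios with opposite sign, if it is the same pool. No single-day value was tested.

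Some of the highest genes for the mean of FVB/N abraded over sham stood above 0 in both ratios on day 30. Sprr1b stood at 2.44 in FVB/N abraded over sham and at 4.86 in Tg.AC over FVB/N, Mrm2 at 3.78 and 4.88, Plxnb3 at 3.68 and 4.63, and Il6ra at 2.07 and 4.74. It is unsure whether the probes named Mrm2, Plxnb3 and Olfr114 by their accessions measure these genes. Interferon response genes had a median of -0.56 on day 3 of FVB/N abraded over sham, below all 10000 random lists, with Iigp1 at -1.88 and Ifi205 at -1.79. Their median was -0.27 on day 30, also below all random lists, and on that day it was 0.20 in Tg.AC over FVB/N, with Ly6e at 1.09. These 2 values mirror each other through the FVB/N abraded pool, if it is the same. On days 9 and 18 of Tg.AC over FVB/N the median was -0.17 and -0.13, below all random lists. The skeletal muscle genes Mstn and Eno3 stood at -3.80 and -3.54 on day 3 of FVB/N abraded over sham, while the list median of -0.14 lay within the random lists.

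Across 20093 genes, which are not independent, FVB/N abraded over sham on day 9 correlated with Tg.AC over FVB/N on day 30 at 0.72, and with day 18 at -0.71. The ribosomal protein genes followed the dye in Tg.AC over FVB/N, with medians of -1.77 and -0.13 on the 2 arrays of day 3 and of -0.44 and 1.02 on day 5.

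The arrays of days 5 and 9 of Tg.AC over FVB/N ran opposite ways once turned. A probe-specific dye effect larger than the strain difference may account for this, since their unturned ratios correlated across probes with the dye effect of the other comparison at 0.616 or more. A wrong dye label on 1 array of a pair cannot be told apart on day 9: with that dye effect taken off, 66.7% of 33 probes at least 2-fold apart had the same sign (95% exact binomial interval 48.2 to 82.0%). On day 5 the share was 73.9% of 23, and the correlation across all probes was still -0.32.

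The count for the mean of FVB/N abraded over sham, 4930, was the highest of 16 sign patterns of the days, 1 of which reached it, and the highest other was 2231. So few patterns cannot give a share under 0.05. Limma's real count was 0 for the mean of Tg.AC over FVB/N and for both trends, and a count of 0 is reached by any pattern or order. It was reached by all 16 sign patterns for that mean, with a highest other of 0. It was reached by 100 of 100 drawn orders of the days for the trend of either comparison, with highest others of 2 and 7. These 3 counts therefore say nothing about chance.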
